A study of Caenorhabditis elegans with 4 samples.

How the data were processed

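The series is a chromatin immunoprecipitation sequencing (ChIP-seq) experiment on Caenorhabditis elegans hermaphrodites at the fed L1 larval stage, grown at 20 °C and crosslinked with 2% formaldehyde. The strain carries EFL-1, an E2F-family transcription factor, fused to GFP and expressed in the intestine from the ges-1 promoter. Per the labels' protocols, chromatin was sheared by sonication, a part of each lysate was kept as Input, and the rest was precipitated with affinity-purified goat antibodies against GFP. The 4 samples are 2 ChIP libraries and 2 Input libraries, both numbered replicates 2 and 3 in the labels. Nothing in the labels says whether the replicates came from separate cultures, so the comparison of the ChIP replicates measures the spread between these samples, which may be technical.

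A peak list was analysed for each ChIP replicate, with a combined list for both. Per the file headers, coordinates are on the WormBase WS220 genome build, and the source column of every row names SPP peaks passed through IDR, a procedure that ranks peaks by their reproducibility between replicates. The aligner, the versions, the IDR threshold and the read numbers are not given in the sources used here. How the authors pooled the replicates for the combined list is not stated either. The Input libraries enter only through whatever use the authors made of them in peak calling.

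Each peak has a chromosome, a start, an end, a number in its name and a deposited score from the authors' peak caller, and the file headers do not name this score. Many peaks share the highest score of a list: 2058 of 2332 in the combined list, 1390 of 30000 in replicate 2 and 2299 of 30000 in replicate 3. Across peaks, the score fell with the number in the peak's name, with a Spearman coefficient of -1.00 in replicate 2, -1.00 in replicate 3 and -0.56 in the combined list, where most scores are tied. Peaks were therefore ranked by score, with ties ordered by that number, and ranks were compared only as ranks within 1 list. The replicate lists stop at exactly 30000 peaks each, so a peak count per replicate carries no information on binding. Sequencing depth is unknown. Intervals given below cover counting error only.

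Peaks of different lists were called shared when they overlapped by at least 1 bp. The best 2332 peaks of each replicate, as many as the combined list holds, were compared, and all 30000. As the rows name IDR, the size of the combined list may itself reflect reproducibility between these replicates. Chance overlap came from 1000 circular shifts, in which every peak of one list was moved along its chromosome by 1 random distance per chromosome, between 5% and 95% of its length (one-sided permutation test, smallest possible p 0.001). Rank agreement was the Spearman coefficient across shared peaks, with each peak used once. It was computed on the ranks within each list, with ties ordered by the number in the peak's name. Chromosome lengths were taken as the largest peak end in the 3 lists, from 13.8 Mb for chromosome III to 20.9 Mb for chromosome V. X was compared with the 5 autosomes by a two-sided exact binomial test on length. Each chromosome was also divided into equal left, central and right parts, and the central share of peak midpoints was tested in the same way. Because neighbouring peaks are not independent, 10000 rotations were added: the whole list was rotated along the joined chromosomes for the X share, each autosome by its own distance for the central share, and the joined autosomes for the density of single autosomes. Intervals on shares and densities are 95% exact Clopper-Pearson intervals unless Wilson is named. Adjusted p-values are Benjamini-Hochberg values.

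The alternatives tried were reciprocal overlap of at least 50%, midpoints within 100 bp, the best 1166 or 4664 peaks, the best 1166 combined peaks, and the best 2332 peaks of either replicate alone in place of the combined list. After the data were seen, 3 more were added: combined peaks shared with the best 2332 of both replicates, and combined peaks merged when their midpoints lay within 5 kb or within 20 kb. The overlap and density scripts were tested on simulated lists of 2000 peaks. With 60% of peaks truly shared, 60.4% were recovered at 1 bp overlap. A simulated X to autosome density ratio of 0.3 gave a mean estimate of 0.30, with 94% of the 100 intervals covering it. The simulated peaks were placed independently of one another, so this checks the scripts and not the coverage of the intervals where sites cluster.

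The main overlap, rank, X against autosome and central share tests and the settings other than those 3 were fixed before the data were examined. The rank test had been planned on scores, and ranks were used in their place. The rotations, the tests of single chromosomes, the central share on X and its comparison with the autosomes under every setting, the McNemar test, the overlap by rank bin, the 1 Mb windows, the comparisons with low-ranked peaks and the tests of the closing section were added later. The rule for naming peaks was also fixed beforehand: the 10 best combined peaks, and the 3 best peaks of each replicate list that overlapped no peak of the other. Analyses by gene, gene list, transgene part and sequence motif had been planned on condition of a genome or annotation on WS220. The gene table at hand is on WBcel235, so none was run, peaks are given by position, and whether a peak lies in a gene, exon, intron or UTR is not stated. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.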

Results

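Binding of EFL-1::GFP, an E2F-family transcription factor tagged with green fluorescent protein and driven by the intestinal ges-1 promoter, was mapped by ChIP-seq in C. elegans larvae at the fed L1 stage. E2F factors are known for binding promoters of cell cycle genes. The combined list held 2332 peaks, also called sites below, and each of the 2 ChIP replicates had its own list of 30000 ranked peaks. No control immunoprecipitation was analysed. Binding of the tagged protein therefore cannot be told apart from open chromatin precipitated without it, in the combined list as well. Both replicates had an Input library, for which no separate list was analysed. Peaks were short: the commonest width was 290 bp in the combined list, shared by 72.2% of its peaks, 304 bp in replicate 2 and 280 bp in replicate 3.

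The combined list was examined first for its best-ranked sites. The 10 given here are among the 2058 combined peaks that share the highest score. Their order, and their choice among these, comes only from the number in the peak's name. The best-ranked peak lay on chromosome II at 4999174 to 4999496 (WS220), and ranked 1 in replicate 2 and 9 in replicate 3. The second lay on chromosome III at 3867381 to 3867704, with ranks 3 and 1. The next was on chromosome II at 10563374 to 10563674 and ranked 2 in both replicates. Chromosome IV carried the peak of rank 4, at 14464057 to 14464354, with replicate ranks 5 and 4. The peak of rank 5 was on chromosome III at 7854441 to 7854757, with replicate ranks 4 and 8. Chromosome V held the peaks of rank 6, at 10897219 to 10897527, with replicate ranks 6 and 5, and of rank 7, at 5939528 to 5939849, with replicate ranks 9 and 6. The peak of rank 8 was on chromosome III at 8741430 to 8741743, with replicate ranks 15 and 7. Chromosome IV also carried the peak of rank 9, at 12724655 to 12724945, with replicate ranks 12 and 10. The peak of rank 10, on chromosome V at 16965676 to 16965964, ranked 7 in replicate 2 and 26 in replicate 3. None of these 10 sites was on chromosome I or X.

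The comparison of the replicates asked how many peaks were found in both libraries. Of the best 2332 peaks of replicate 2, 1564 overlapped one of the best 2332 of replicate 3, which is 67.1% (Wilson 95% interval 65.1 to 68.9%). In the other direction the share was 66.8% (64.9 to 68.7%). Circular shifts gave 1.40% on average and at most 2.23% for replicate 2, so the overlap exceeded all 1000 shifts (permutation test, one-sided, p = 0.001, the smallest these shifts can give). The same held in the other direction, where shifts gave 1.41% on average (permutation test, one-sided, p = 0.001). Shared sites lay close together: the median distance between the midpoints of the 1550 pairs was 16 bp, and 94.5% were within 100 bp. Across these pairs the ranks in the replicates had a Spearman coefficient of 0.88. The highest score was shared by 1390 peaks in replicate 2 and 2299 in replicate 3. Among those peaks the ranks come only from the number in the peak's name, so this coefficient largely compares these numbers and not scores. Pairs of peaks are not independent replicates, so no p-value is attached.

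Over the full lists, 30.5% of the 30000 peaks of replicate 2 and 30.4% of those of replicate 3 overlapped the other list, against 16.97% and 16.95% in shifted lists (permutation test, one-sided, p = 0.001 for each). Across the 8853 pairs the Spearman coefficient was 0.56. The share of common peaks depended on rank. Among the first 1000 peaks, 99.7% of replicate 2 and 99.6% of replicate 3 had a partner in the other list. For ranks 1001 to 2000 the shares were 81.9% and 85.6%, and for ranks 2001 to 3000 they were 47.5% and 58.9%. The best 1166 peaks of each list shared 83.1% and 83.3%, and the best 4664 shared 45.6% and 45.7%.

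**Figure D1:**
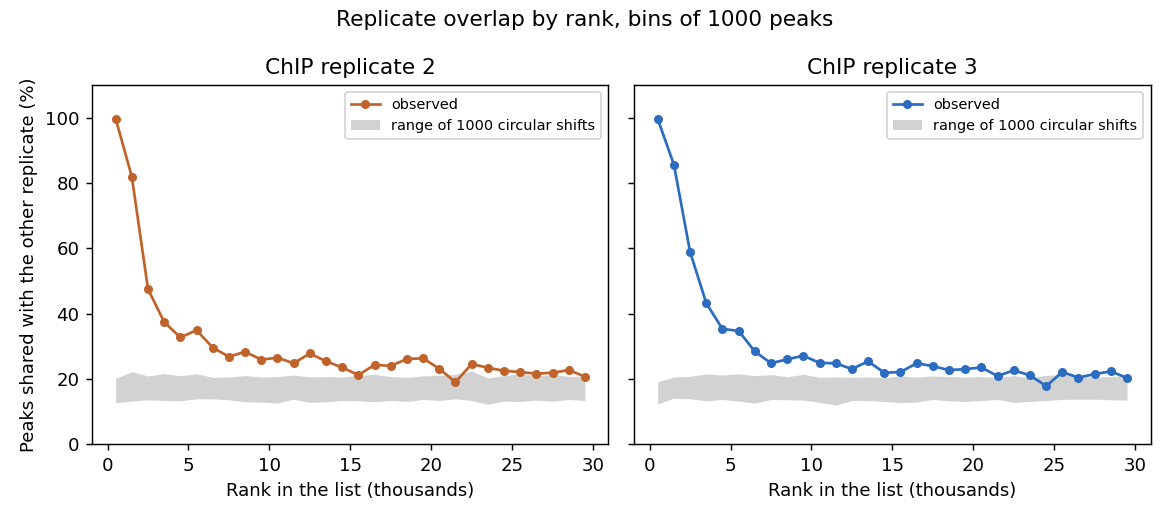
Share of peaks, in percent, that overlapped any peak of the other replicate (points), against rank in bins of 1000 peaks, for replicate 2 (left) and replicate 3 (right). The grey band is the range of 1000 circular shifts; the first bin holds 99.7% and 99.6% shared peaks, and the share then falls towards the band.

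Best-ranked peaks without any counterpart were a minority. Of the best 2332 peaks, 341 of replicate 2 (14.6%) and 263 of replicate 3 (11.3%) overlapped none of the 30000 peaks of the other list. Circular shifts of that list still overlapped 16.8% and 16.4% of these best peaks on average, so some counterparts may be accidental. The best-ranked such peaks of replicate 2 were on chromosome I at 8965885 to 8966188 (rank 840), on chromosome IV at 8587042 to 8587345 (rank 879) and on chromosome II at 7664199 to 7664502 (rank 907). Those of replicate 3 were on chromosome III at 5785657 to 5785731 (rank 618), on chromosome I at 13463812 to 13464091 (rank 930) and on chromosome III at 9717119 to 9717398 (rank 955). All 6 have the highest score of their list, so these ranks come from the number in the peak's name. The combined list held 5 of these 6 sites, all but the one on chromosome II. The nearest midpoint in the other replicate was 337 bp away for that site and 7856 bp away for the first site on chromosome III.

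The combined list was then set against the replicates it was made from, so part of the shares below is built in. Of its 2332 sites, 2218 overlapped a peak of replicate 2 (95.1%, Wilson 95% interval 94.2 to 95.9%) and 2329 a peak of replicate 3 (99.9%, 99.6 to 99.96%). Among the best 2332 peaks of a replicate, 1721 combined sites (73.8%) were found in replicate 2 and 2102 (90.1%) in replicate 3. Both sets held 1556 sites (66.7%), 546 were in the set of replicate 3 alone, 165 in that of replicate 2 alone, and 65 in neither. The 546 and 165 sites differed by more than counting error (exact McNemar test, two-sided, p = 1.8e-48), so by this count the combined list was closer to replicate 3. The test treats sites as independent, and its p-value concerns these lists only. How the replicates were pooled is not stated, so an equal split need not be what the pooling would give. The 114 combined sites with no peak in replicate 2 had a median rank of 1994 in the combined list.

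The distribution of sites over the chromosomes differed from that of the chromosomes' lengths. The X chromosome carried 143 combined sites, or 8.07 per Mb (95% interval 6.83 to 9.46), against 2189 sites, or 26.5 per Mb, on the autosomes. X thus held 6.13% of the sites (5.19 to 7.18%) on 17.7% of the length, a density ratio of 0.30 (0.26 to 0.36; two-sided exact binomial test, p = 8.7e-61). Both replicates showed the deficit in their best 2332 peaks, with ratios of 0.31 (0.26 to 0.37) in replicate 2 and 0.36 (0.31 to 0.43) in replicate 3. The deficit was deeper in 2 narrower sets: the ratio was 0.16 (0.11 to 0.22) for the best 1166 combined sites and 0.20 (0.15 to 0.25) for the sites found in the best 2332 of both replicates. The best 1166 all share the highest score and were set apart only by the number in the peak's name. It was 0.48 (0.39 to 0.58) when sites within 20 kb were merged. Of 10000 rotations of the whole list, 4 equalled the observed X share of 6.13% and 0 gave a lower one (two-sided permutation test, p = 0.001). Rotations by a very small distance return nearly the real list, and few separate stretches as long as X fit in the genome. The rotations therefore show that no rotated stretch of that length was sparser than X, and the size of this p carries little more.

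Replicate peaks ranked 15001 to 30000 were spread over X nearly in proportion to its length. X held 17.2% of them in replicate 2 (16.6 to 17.8%) and 16.8% in replicate 3 (16.2 to 17.4%). The share in replicate 3 was slightly below the 17.7% of the length (two-sided exact binomial test, p = 0.0063). The combined list differed from both (Fisher's exact test, two-sided, p = 4.8e-51 and p = 2.1e-48).

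**Figure D2:**
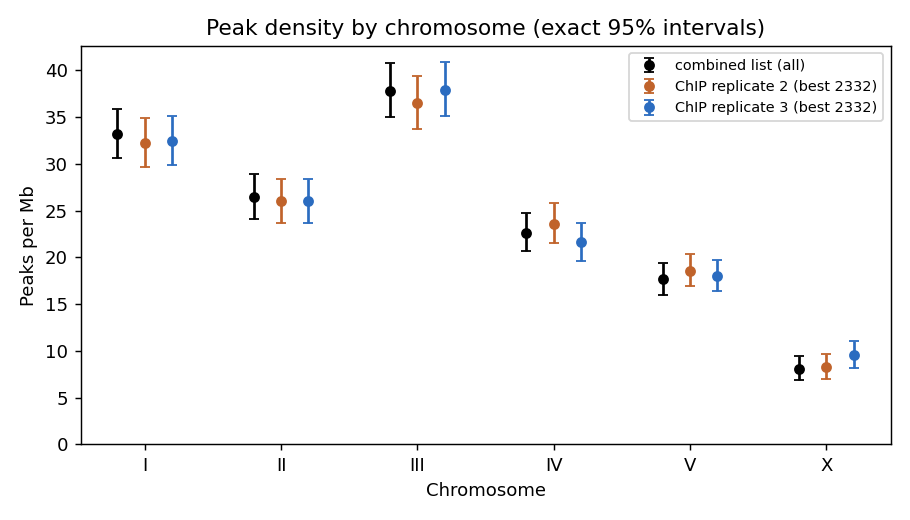
Peaks per Mb on each chromosome in the combined list (black) and among the best 2332 peaks of replicate 2 (orange) and replicate 3 (blue), with exact 95% intervals as bars. Chromosome X has 8.07 combined peaks per Mb, below each autosome, and chromosome III has 37.8.

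Among the autosomes, chromosome III was the densest with 521 sites, or 37.8 per Mb (35.0 to 40.8). Chromosome I had 499 sites, or 33.1 per Mb (30.6 to 35.8), chromosome II 26.4 per Mb, chromosome IV 22.6 per Mb and chromosome V 17.6 per Mb (16.01 to 19.4). Relative to the autosomal mean the density was 1.43 on chromosome III (1.32 to 1.54), 1.25 on chromosome I (1.15 to 1.35), 0.85 on chromosome IV (0.78 to 0.93) and 0.66 on chromosome V (0.60 to 0.73). These departures passed an exact binomial test, with adjusted p = 5.2e-17, 1.5e-07, 0.00042 and 8.5e-21, while chromosome II did not (adjusted p = 0.98). They did not pass rotations of the autosomes, which keep the spacing of sites: the adjusted p was 0.31 for chromosome III, 0.60 for chromosome I, 0.77 for chromosome IV and 0.19 for chromosome V (permutation test, two-sided). The order of the 5 autosomes was the same in the best 2332 peaks of each replicate.

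Along the autosomes, sites were more frequent in the central part than in the outer parts. The central part held 901 of 2189 autosomal sites, 41.2% (39.1 to 43.3%), where equal density would give 33.3% (two-sided exact binomial test, p = 2.3e-14; 10000 rotations within chromosomes, two-sided permutation test, p = 0.0012). The central share was 45.3% on chromosome V (40.1 to 50.5%), 41.8% on chromosome III (37.6 to 46.2%), 40.3% on chromosome II, 39.5% on chromosome I and 39.4% on chromosome IV, and each passed the exact binomial test after adjustment over 6 chromosomes, with the highest adjusted p = 0.015 on chromosome IV. That test treats sites as independent. Rotations of the central share were run only for the full combined list over all autosomes, so no single chromosome or other setting was tested against them. It was 42.4% in the best 2332 peaks of replicate 2 and 40.5% in those of replicate 3. It was smaller in the best 1166 combined sites, at 37.9% (35.1 to 40.8%; exact binomial test, p = 0.0011), and after merging within 20 kb, at 37.6% (34.8 to 40.5%; exact binomial test, p = 0.0023). Autosomal replicate peaks ranked 15001 to 30000 had smaller central shares, 35.3% in replicate 2 and 34.7% in replicate 3, with odds ratios of 1.28 and 1.32 for the combined list against them (Fisher's exact test, two-sided, p = 1.4e-07 and p = 8.3e-09). This comparison was made for the full combined list only. The intervals for the best 1166 sites and for sites merged within 20 kb both include the 35.3% of replicate 2.

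On X the central part held 43 of 143 sites, 30.1% (22.7 to 38.3%), with no difference from 33.3% detected (two-sided exact binomial test, p = 0.43). In the best 2332 peaks of replicate 2 alone the share lay on the other side of 33.3%, at 36.3% (28.5 to 44.7%; exact binomial test, p = 0.48). The central shares of autosomes and X differed with an odds ratio of 1.63 (Fisher's exact test, two-sided, p = 0.011). By the same Fisher's exact test, that difference held in replicate 3 alone (odds ratio 1.49, p = 0.022) and after merging within 5 kb (1.63, p = 0.013). It did not pass that exact test in replicate 2 alone (odds ratio 1.29, p = 0.17), in the best 1166 combined sites (1.32, p = 0.50), in the sites found in both replicates (1.53, p = 0.15) or after merging within 20 kb (1.30, p = 0.23). These Fisher's exact tests treat sites as independent, and no rotations were run for this comparison.

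**Figure D3:**
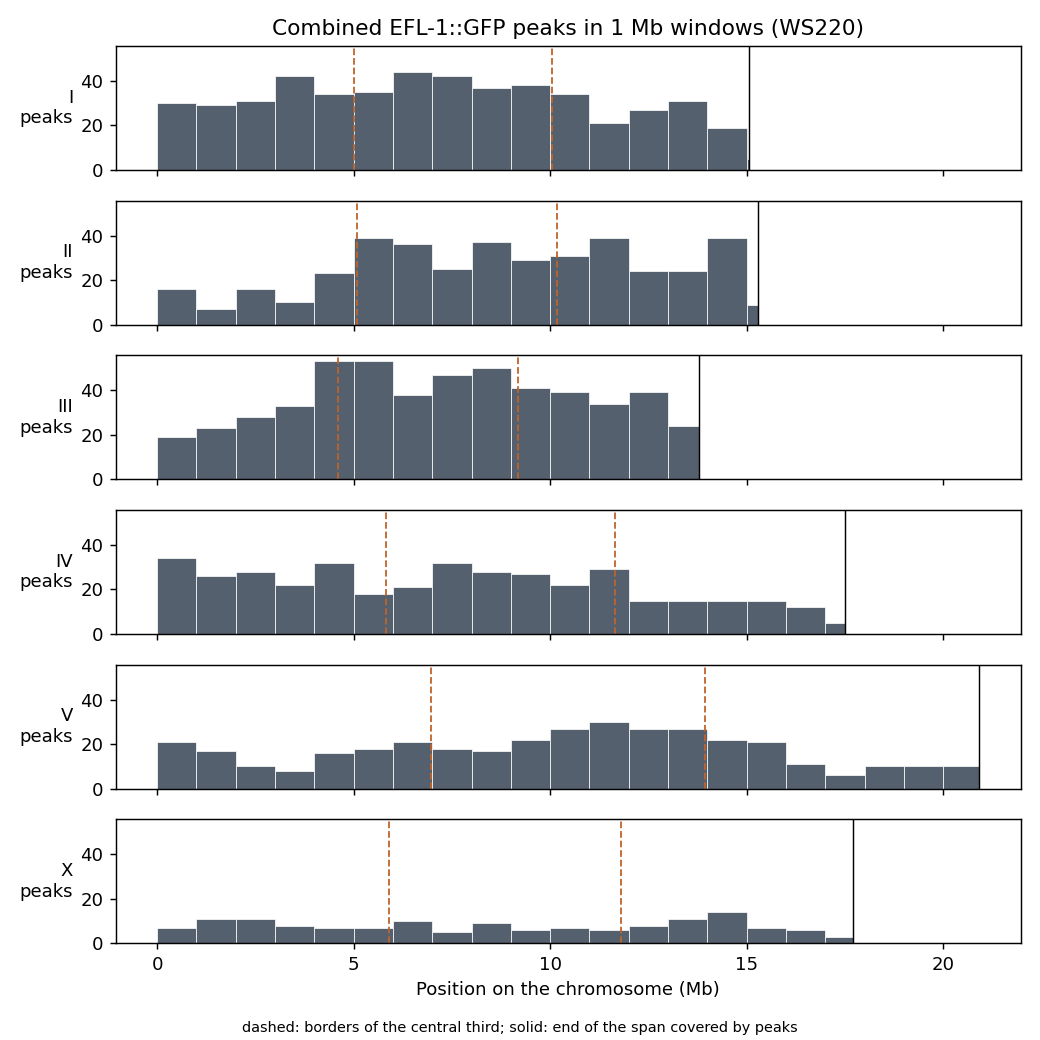
Number of combined peaks in 1 Mb windows along each chromosome (WS220), with dashed lines at the borders of the central part and a solid line at the last peak end. The fullest windows, with 53 peaks each, are on chromosome III at 4 to 6 Mb, and no X window exceeds 14.

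In windows of 1 Mb the median number of sites was 39 on chromosome III, 34 on chromosome I, 25 on chromosome II, 22 on chromosome IV, 18 on chromosome V and 7 on X. The fullest windows were on chromosome III from 4000001 to 5000000 and from 5000001 to 6000000, with 53 sites each, followed by 50 sites from 8000001 to 9000000 on the same chromosome. Chromosome I reached 44 sites from 6000001 to 7000000. Every X window of at least 0.9 Mb held between 5 and 14 sites.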

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

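The test of local shifts and the test beyond 1 kb were set up before their results were seen.

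Replicate peaks below the combined list also recurred between the replicates more often than chance. Of the peaks ranked 2333 to 10000 and over 1 kb from any combined site, 27.5% of replicate 2 and 30.98% of replicate 3 overlapped a peak of the other replicate. These peaks belong to no comparison of the combined list, and the values lie above those of shifted lists. When the other list was moved by 5 to 50 kb, which keeps regional density, the means were 14.96% and 15.2% and the highest of 1000 shifts were 16.4% and 16.6%. The excess amounts to 864 peaks in replicate 2 and 1056 in replicate 3. Regional density of peaks as the whole cause is argued against by the smallest excess over the highest local shift, 10.6 percentage points among all such peaks outside the combined list, and shoulders of combined peaks by the corresponding 11.1 percentage points beyond 1 kb. Weak sites of EFL-1::GFP may account for this excess, and so might open chromatin precipitated without the tagged protein. The latter was not tested, because no control immunoprecipitation was analysed here, and no biological explanation was tested because the design has a single condition.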

How the results depend on the processing

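Of the 22 results under other settings fixed before the data were examined, 18 kept their direction and side of the threshold. The other 4 moved in value under reciprocal overlap of 50% and had no threshold to cross. For 18 more results the setting or the result itself was added after the data were seen, and 13 of them kept both. These 18 include the central share on X and its comparison with the autosomes. Requiring reciprocal overlap of 50% changed the Spearman coefficient from 0.56 to 0.62 over all pairs and from 0.88 to 0.86 in the best 2332. It lowered the share of combined sites found in replicate 2 from 95.1% to 83.3% and in replicate 3 from 99.9% to 97.3%. The cause was not tested. The same rule gave 56.9% shared among the best 2332 of either replicate, and midpoints within 100 bp gave 63.0%, both above all shifts. The X to autosome ratio with a single replicate ranged from 0.31 to 0.36, and the autosomal central share from 40.5% to 42.4%. The latter was 37.9% in the best 1166 sites, 39.8% in the sites found in both replicates, 40.9% after merging within 5 kb and 37.6% after merging within 20 kb. The central share on X ranged from 31.4% to 36.3% with a single replicate and was above 33.3% in replicate 2 alone, and the cause was not tested. The odds ratio of autosomes against X for the central share ranged from 1.29 to 1.49 with a single replicate, was 1.32 in the best 1166 sites, 1.53 in the sites found in both replicates and 1.30 after merging within 20 kb. All of these but the 1.49 of replicate 3 missed the threshold of 0.05, and the last 3 settings also have fewer sites. No paired analysis was possible because the Input libraries, which share the replicate numbers of the ChIP libraries, have no values here. The other settings for position relative to genes, gene lists, peak strength by gene list and sequence motifs were not run, for want of an annotation and a genome on WS220. Read depth is unknown, so it cannot be said how far it limits replicate 2 against replicate 3.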

Other observations

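The tests of low-ranked peaks and of the score steps were chosen after the result was seen, as were the merging of sites, the spacing and the rank comparison. The single-replicate lists had been fixed before the data were examined, but their use as a test of the X pattern was set out after their values were seen.

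Combined sites on X ranked later as well as being fewer. Their mean rank was 1550, against 1141 for autosomal sites, where a higher number is a later rank (permutation test with 100000 resamples, two-sided, p = 2e-05, the smallest these can give). The 2058 combined sites with the highest score are ordered only by the number in the peak's name, so most of this ranking does not come from the score. Of the 143 X sites, 38 were among the best 1166 and 105 among the rest. Combined sites also lay in short runs: 16.8% had another site within 2 kb, against 11.6% on average when each site was moved at random by up to 50 kb (permutation test, one-sided, p = 0.001, the smallest possible). Within 5 kb the shares were 34.6% and 26.2%. Within 1 kb they were 8.06% and 6.02%, and there the moved sites reached up to 8.53%, above the observed share (permutation test, one-sided, p = 0.005). Merging at 5 kb left 1881 runs, of which 1524 were single sites and 19 held 4, the largest number. One run of 4 spans 10562544 to 10567787 on chromosome I, and another 4698348 to 4706653 on chromosome II.

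The low number of combined sites on X has several candidate explanations. Poorer detection of peaks anywhere on X would lower the X share of replicate peaks ranked over 15000. The lower of the 2 shares was 16.8%, near the 17.7% of the length, so low-ranked calls were not scarce on X. Few of these peaks recurred beyond shifted lists. For ranks 15001 to 16000, for example, 21.2% of replicate 2 and 22.1% of replicate 3 did, against 16.9% and 17.1% in shifted lists. Their spread therefore cannot show how well bound sites on X are detected. Dense autosomal runs counted many times are argued against as the whole cause by the ratio of 0.48 after merging within 20 kb, and an effect of one replicate only by the higher single-replicate ratio of 0.36. X sites falling below the threshold of the combined list stays open as a hypothesis: for shared peaks beyond chance that rank below the list, the X to autosome ratio was 0.86 (95% bootstrap interval 0.66 to 1.08) in replicate 2 and 0.73 (0.58 to 0.90) in replicate 3, both above the 0.30 of the combined list. Those weaker peaks could also be unrelated to EFL-1::GFP, and gene density on X was not tested.

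The scores rise in steps that suggest how they were made. A candidate explanation is that the score is minus log10 of an empirical false discovery rate, (c + 0.5) / (r - 0.5), with r the number in the peak's name and c the calls made in a control. Solving for c gave a whole number within 0.001 for 54.4% of peaks in replicate 2 and 53.8% in replicate 3, where 0.2% would be due to chance. With peaks that share a score with another, which such a rate would also produce once it is made monotone, 85.8% and 89.6% are covered. In the combined list 11.96% of peaks gave a whole number and the other 88.04% are tied. All of its peaks (100%) are thus covered, though most of them only through ties. Under this reading of the score, the peak numbered 2332 has 71 control calls above it in replicate 2, 1 in replicate 3 and 10 in the combined list.

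Peak widths differed between rank bins of the combined list. The median was 252 bp for ranks 1 to 234, 192 bp for ranks 235 to 467 and 138 bp for ranks 468 to 700, and from rank 701 on the median was 290 bp in each of the remaining rank bins. The smallest widths were 72 bp in the combined list, 76 bp in replicate 2 and 70 bp in replicate 3.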
